A study of Mus musculus with 14 samples.

How the data were processed

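Poly(A)-selected RNA from mouse embryonic stem cells of the J1 line was sequenced in 14 libraries that form 7 groups of 2. The authors deposited 2 tables of counts, whole numbers of reads per gene and library with no normalization, 1 table for each experiment. Per the submitters' processing notes, Bowtie 0.12.8, TopHat2 2.0.2, HTSeq 0.5.3p9 and the genome build mm9 were used. The strand setting and the gene annotation release are not given in the sources used here, and neither are the inhibitor's dose and duration. A read in an exon shared by overlapping genes therefore cannot be assigned to one of them by strand here, and the overlap is stated at each named gene concerned. How such reads were counted is not known here. They may be missing from a named gene or come from its neighbour.

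Each table held 37991 Ensembl gene IDs, of which 32919 matched a symbol in a GENCODE mouse annotation of a later build than mm9. Only symbols, chromosome membership, biotype and gene order were taken from that annotation, and no coordinates are given. IDs without a match held between 0.482% and 0.85% of a library's counts.

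Libraries held 25588815 to 37399837 counts in experiment 1 and 23354015 to 41844823 in experiment 2. A gene with 0 counts in both libraries of a group was given a floor of 3 counts over the group, and a ratio against it is a lower bound. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

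The experiments were fitted separately in edgeR 4.0.16 under R 4.3.3 with limma 3.58.1. Genes were kept by filterByExpr on the groups, with a minimum count of 10 and a minimum total of 15, which left 16711 genes in experiment 1 and 16303 in experiment 2. TMM factors scaled the libraries. All groups of an experiment shared 1 quasi-likelihood fit without covariates, with 4 residual degrees of freedom in experiment 1 and 3 in experiment 2. Contrasts were tested by the two-sided quasi-likelihood F-test, and p-values were adjusted by Benjamini-Hochberg over the genes tested. A gene was called at an adjusted p under 0.05. The biological coefficient of variation was 3.73% in experiment 1 and 10.5% in experiment 2. The labels number the replicates but do not say that they were separate cultures, so p-values measure only the spread between these samples, which may be technical.

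There were 8 comparisons. Those of experiment 1 were genotype under vehicle, inhibitor in wild-type cells, inhibitor in TKO cells, both together against neither, and the interaction of inhibitor and genotype. Those of experiment 2 were the 3 pairs of genotypes. Genes called in one experiment were also measured in the other, which shares no library with it.

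A set of 26 gene lists was written from general knowledge, none taken from the study. They cover germline genes reported to be held silent by promoter methylation, meiosis, the piRNA pathway, X-linked germline genes, imprinted genes, 2-cell-stage genes, developmental regulators, Hox genes, pluripotency, primed epiblast, endoderm, trophoblast, fibroblast and neural ectoderm markers, DNA methylation machinery and polycomb components. The others cover p53 targets, the integrated stress response, NRF2 targets, heat shock, AhR targets, the interferon response, cholesterol synthesis, glycolysis and hypoxia, proliferation and mitochondrially encoded genes. Lists were matched by symbol. List counts, medians and tests cover only members kept by the filter. A member silent in one group could pass it through the group where it was high. For lists near-silent in wild-type cells, the share rising in TKO cells can be raised by this. Members of the Rhox, Xlr, Magea, Zscan4, prolactin and Hspa1 families are near-identical in sequence and may share reads or lose them in counting.

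Each list was tested by camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 26 lists of a comparison. Camera was repeated with the correlation estimated from the data. With it, the list calls held only for X-linked germline genes under vehicle and under both perturbations, and for endoderm markers in the interaction. The rotation test fry was also run. It asks whether a list's genes move, on balance, one way, or in its mixed form in either direction, without reference to other genes.

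Genes named in the text came from a rule. It took the targeted genes Dnmt1, Dnmt3a, Dnmt3b and Tet1 with Tet2 and Tet3, and a set of anchor genes, both whether called or not. It also took from each list up to 4 called members per direction with the smallest p, and the 10 called genes with the largest rise and the 10 with the largest fall. The list and largest-change parts required non-overlapping libraries, except for the interaction, and the last part required a mean of at least 1 CPM and skipped unnamed gene models. Genes were left out for length, and 1 gene that the rule took is not reported here. The groups, tests, gene lists, naming rule and the alternatives were fixed before the data were examined, except those described as chosen afterwards.

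The tests were tested on simulated data, with fold changes imposed on counts drawn from the wild-type profile of each experiment. Only well-covered genes were changed, 67 at 2-fold and 67 at 1.5-fold in each simulation, rising and falling in similar numbers. At a 2-fold change 94.0% of changed genes were recovered in the simulation of experiment 1 and 80.6% in that of experiment 2. At 1.5-fold the shares were 86.6% and 34.3%. False calls made up 2.11% and 4.76% of the calls. These rates hold where few genes change, whereas the real contrasts of TKO with wild type called 69.0% of genes under vehicle and 50.2% untreated. Camera gave a p of 1.04e-51 and 5.06e-35 to a list with raised members, and gave none of 100 null lists a p under 0.05 in either. Simulated genes were drawn independently, so these null lists do not test camera on correlated genes.

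Alternatives were DESeq2 size factors, library size only, no filter, a filter of at least 1 CPM in 2 libraries, DESeq2 1.42.0 Wald tests, limma-voom, only the compared groups, a replicate block, an adjusted p under 0.01, a log2 fold change over 1, and leaving out each library in turn. Replicate numbers were checked by the correlation across genes of same-numbered libraries' deviations from their group means. It lay between -0.034 and 0.038 in the 6 pairs of groups of experiment 1, where the numbers share only a label. In the 3 pairs of experiment 2 it lay between 0.111 and 0.236, so these libraries were taken as paired, from the data alone since the labels name no shared batch. The values given for experiment 2 still come from the planned fit, which has no block and ignores this pairing. The blocked value is given beside each named-gene or list call it changed and beside each total of called genes. The column taken as Tet1-KO TKO replicate 1 carries a letter after its number that the labels do not explain, so the pairing, the block and the replicate numbers of this group rest on that assignment, while its group does not. The block was planned for the germline list, and other lists of experiment 2 were tested with it afterwards. Tests without genes of chromosomes 1, 8 and Y were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.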

Results

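Messenger RNA was measured in J1 mouse embryonic stem cells in 2 experiments. Experiment 1 crossed genotype with treatment in 4 groups: wild-type cells and cells lacking the DNA methyltransferase genes Dnmt1, Dnmt3a and Dnmt3b (TKO cells), each with the vehicle DMSO or with PRT4165, an inhibitor of the polycomb complex PRC1. Experiment 2 held 3 groups of untreated cells: wild type, TKO, and TKO cells that also lacked Tet1 (Tet1-KO TKO), which encodes an enzyme that oxidises methylated cytosine. Each group had 2 libraries. Replicates 1 and 2 held 29384595 and 33822844 counts in wild-type vehicle cells, 37399837 and 25588815 in wild-type inhibitor cells, 28053134 and 28339620 in TKO vehicle cells, and 34949194 and 30659634 in TKO inhibitor cells. In experiment 2 they held 28043647 and 23354015 counts in wild type, 34270373 and 30071029 in TKO and 37716145 and 41844823 in Tet1-KO TKO. Levels below are CPM (read counts scaled by TMM to a common library size) as mean ± SD with n = 2 libraries per group, and changes are log2 fold changes with their standard error (SE) from edgeR.

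The first comparison asked what loss of the DNA methyltransferases did to transcripts, and to germline genes above all, in vehicle-treated cells. Genotype and line are confounded in it, so a change cannot be assigned to methyltransferase loss alone. Transcripts of the targeted genes fell but persisted. Dnmt1 fell from 429 ± 6.97 to 128 ± 0.0613 CPM (log2 change -1.75, SE 0.05) and Dnmt3b from 188 ± 13.2 to 42.6 ± 1.93 CPM (-2.14, SE 0.06). Dnmt3a, which overlaps another gene, fell by 1.28 (SE 0.05). In single libraries Dnmt1 stood at 424 and 434 CPM in wild-type and at 128 and 128 CPM in TKO vehicle cells. Tet1 rose by 0.28 (SE 0.06) and Tet3 by 0.47 (SE 0.07), while Tet2 fell by 0.63 (SE 0.05). Dnmt3l, a cofactor of the de novo methyltransferases that also shares exon sequence with another gene, rose from 132 ± 8.03 to 719 ± 10.5 CPM (2.44, SE 0.05).

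Of the 39 germline genes listed as silenced by methylation, 29 rose, 6 fell and 4 were not called, with the same 29 and 6 when adjusted over the list alone. Dazl, an RNA-binding regulator of germ cell entry, rose from 9.27 ± 0.979 to 87.3 ± 2.97 CPM (3.24, SE 0.07, adjusted p = 2.9e-22). Fkbp6, needed for piRNA production and meiosis, rose from 1.41 ± 0.121 to 42.3 ± 0.86 CPM (4.90, SE 0.10), and the meiotic cohesin gene Smc1b from 4.04 ± 0.654 to 44.2 ± 0.571 CPM (3.46, SE 0.10). Hormad1, a protein of the meiotic chromosome axis, rose by 2.69 (SE 0.08), Rpl10l by 2.12 (SE 0.06), Taf7l by 1.91 (SE 0.16), Tex101 by 2.55 (SE 0.23), Slc25a31 by 1.34 (SE 0.14), Sycp1 by 1.32 (SE 0.11) and Stk31 by 0.81 (SE 0.07). Brdt, a chromatin reader of the testis, fell from 8.14 ± 0.707 to 0.957 ± 0.122 CPM (-3.09, SE 0.19). Mael, a piRNA factor on chromosome 1, fell by 0.51 (SE 0.08), and the genes of that chromosome had a median 0.49 below that of the other autosomes. Sycp3, which overlaps another gene, stood at 1.70 ± 0.125 against 2.16 ± 0.0708 CPM (adjusted p = 0.122). The list's median was 0.81 (camera adjusted p = 0.00012), with an adjusted p = 0.113 for an estimated correlation. Ddx4 fell by 0.20 (SE 0.07), a call lost without TKO vehicle replicate 2 (-0.17, adjusted p = 0.104), with library size only and in DESeq2, where adjusted p over its alternatives ranged from 0.0121 to 0.498.

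**Figure D1:**
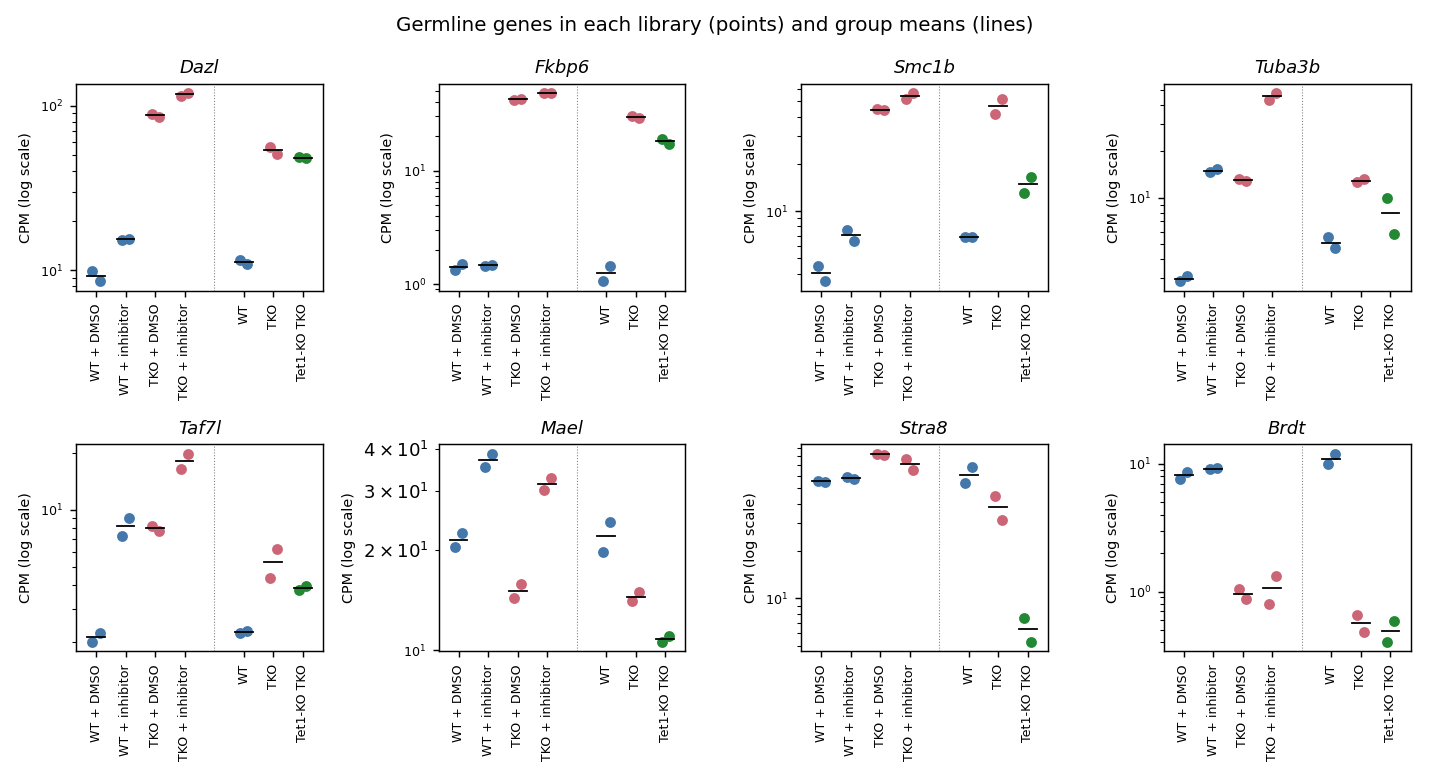
CPM on a log axis for 8 germline genes, with points for the 2 libraries of each group and lines for group means, experiment 1 left of the dotted line and experiment 2 right of it. Dazl stood at 9.27 CPM in wild-type vehicle cells, 87.3 CPM in TKO vehicle cells and 48.2 CPM in Tet1-KO TKO cells, while Stra8 stood at 37.9 CPM in untreated TKO and 6.41 CPM in Tet1-KO TKO cells.

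Several other germline and early-embryo groups also rose. Of 37 X-linked germline genes 35 rose and 1 fell (36 and 1 adjusted over the list alone), with a median of 6.40, or 4.70 with the 12 members at 0 in 1 group placed at their bound (camera adjusted p = 1.4e-13, and adjusted p = 0.0208 with an estimated correlation). Xlr3c rose from 0.336 ± 0.08 to 43.8 ± 0.0477 CPM and the homeobox gene Rhox9 from 1.89 ± 0.256 to 56.5 ± 2.85 CPM. Rhox6 rose from 2.83 ± 0.795 to 63.4 ± 1.78 CPM, and Magea4, at 0 counts in both wild-type libraries, was at least 105-fold higher. These families may share reads. Other listed members, such as Rhox8, Rhox11 and Mageb1, were counted but failed the filter. Members at 0 in 1 group passed it only through other groups, so 35 of 37 holds for tested members alone. All 27 tested 2-cell-stage genes rose (27 and 0 adjusted over the list alone; median 5.12, or 4.61 at the bound; adjusted p = 1.6e-09, and 0.113 as the adjusted p with an estimated correlation). Zscan4d rose from 0.210 ± 0.209 to 15.4 ± 1.06 CPM and Tmem92 from 0.216 ± 0.00236 to 11.9 ± 2.47 CPM. In the meiosis list 24 of 40 rose and 6 fell (25 and 6 adjusted over the list alone; median 0.63, adjusted p = 0.0059, and 0.232 as the adjusted p with an estimated correlation). In the piRNA list 15 of 30 rose and 8 fell (adjusted p = 0.135), and its member Tdrd12 rose by 3.05 (SE 0.07).

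Imprinted genes and markers of other lineages moved too. Of 52 imprinted genes 35 rose and 15 fell (35 and 16 adjusted over the list alone; median 0.86, camera adjusted p = 0.0059, and adjusted p = 0.113 with an estimated correlation). H19, a maternally expressed noncoding RNA that overlaps another gene, rose from 0.548 ± 0.0169 to 1398 ± 43 CPM (11.30, SE 0.09). Peg3 rose by 3.76 (SE 0.06), Peg10 by 2.59 (SE 0.05) and Sfmbt2 by 4.33 (SE 0.06). Among 28 trophoblast markers 24 rose and 2 fell, the same counts adjusted over the list alone (median 3.10, camera adjusted p = 2.2e-08, and adjusted p = 0.113 with an estimated correlation). The keratin genes Krt18 and Krt8 rose by 4.01 (SE 0.07) and 3.08 (SE 0.06), Krt19 rose by 4.19 (SE 0.08), and Tead4, a factor of early trophectoderm, fell by 2.07 (SE 0.07). Of 130 developmental regulators 80 rose and 20 fell (82 and 20 adjusted over the list alone; median 1.94, or 1.80 at the bound; adjusted p = 9.7e-06, and 0.113 as the adjusted p with an estimated correlation). Hand1 rose from 0.327 ± 0.109 to 43.5 ± 4.35 CPM and Pax6, a regulator of eye and neural development, from 0.721 ± 0.212 to 30.9 ± 0.452 CPM, while Prrx2 fell by 3.35 (SE 0.11).

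Of 40 pluripotency genes 17 rose and 21 fell (median -0.14, adjusted p = 0.477). Klf5 fell from 522 ± 80.5 to 66.8 ± 0.443 CPM (-2.96, SE 0.07). Tfcp2l1, on chromosome 1, fell by 1.82 (SE 0.05), Pou5f1 by 0.78 (SE 0.05) and Nanog by 0.44 (SE 0.04). Tfcp2l1 and Pou5f1 each overlap another gene. Dppa3, expressed in germ cells and the early embryo, rose from 0.710 ± 0.095 to 15.9 ± 0.939 CPM. Sox2 fell by 0.13 (SE 0.04), a call lost without TKO vehicle replicate 1 (-0.12, adjusted p = 0.0942) or replicate 2 (-0.13, adjusted p = 0.0694). With library size only its value was 0.02 (adjusted p = 0.623), and adjusted p ranged from 0.000515 to 0.623 over its alternatives.

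The largest falls included Nkx6-3, on chromosome 8, from 29.3 ± 2.63 to 0.235 ± 0.189 CPM, and the prostaglandin synthase gene Ptges from 135 ± 3.92 to 7.71 ± 1.48 CPM. Of 40 genes of the integrated stress response 28 fell and 7 rose (median -0.44, adjusted p = 0.00028, and 0.113 as the adjusted p with an estimated correlation), and its factor Atf4 fell by 2.15 (SE 0.05). Of 40 proliferation genes 26 fell and 5 rose (adjusted p = 0.00071, and 0.261 as the adjusted p with an estimated correlation). Primed epiblast genes rose in 16 of 22 and fell in 5 (adjusted p = 0.0059, and 0.113 as the adjusted p with an estimated correlation), fibroblast markers in 17 of 29 with 5 falling (0.0053 and 0.152), neural ectoderm markers in 15 of 20 with 1 falling (0.00022 and 0.152) and p53 targets in 28 of 41 with 7 falling (0.0037 and 0.152). Hmox1, a haem oxygenase of the NRF2 list on chromosome 8, rose by 2.19 (SE 0.05). The remaining lists gave no camera call. Rises and falls were 11 and 4 of 23 for Hox genes, 7 and 15 of 27 for endoderm markers, 7 and 15 of 29 for DNA methylation machinery, 18 and 17 of 39 for polycomb components and 13 and 13 of 35 for NRF2 targets. They were 8 and 10 of 23 for heat shock genes, 4 and 2 of 8 for AhR targets, 20 and 10 of 38 for interferon response, 6 and 9 of 24 for cholesterol synthesis, 10 and 14 of 33 for glycolysis and hypoxia, and 2 and 1 of 14 for mitochondrial genes. For endoderm markers, polycomb components, NRF2 targets, heat shock genes and glycolysis the mean was above 0 while the median and the test pointed down.

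In all, 5819 genes rose and 5712 fell of 16711 tested by edgeR, 3196 and 1074 of them by more than 2-fold. Library size scaling alone shifted the median of all genes by 0.15 and gave 63.5% of calls rising against 50.5%. Genes of chromosome 1 had a median 0.49 below that of the other autosomes and genes of chromosome 8 a median 0.33 above it. The difference was not uniform along chromosome 8, whose 4 equal parts by gene order differed from the autosomes other than 1 and 8 by 0.48, 0.55, 0.29 and -0.10 under vehicle, and by 0.43, 0.43, 0.23 and -0.06 in untreated cells. The Y-linked gene Ddx3y stood at 1.42 ± 0.115 CPM in wild-type and 102 ± 2.9 CPM in TKO vehicle cells, so genotype and the expression level of these chromosomes differed together between the lines.

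The next comparison asked what the PRC1 inhibitor did in wild-type cells. Heat shock genes rose together: 21 of 23 rose and none fell (22 and 0 adjusted over the list alone; median 0.43, adjusted p = 2e-12, and 0.131 as the adjusted p with an estimated correlation). The chaperone genes Hspa1a and Hspa1b, near-identical copies that may share reads, rose from 1.03 ± 0.393 to 1226 ± 209 CPM and from 10.8 ± 0.559 to 2881 ± 464 CPM. Hspa1a also overlaps another gene. Hsph1 rose by 2.84 (SE 0.06) and Dnajb1 by 2.20 (SE 0.06). The stress factor Atf3 rose from 1.98 ± 0.335 to 23.5 ± 0.112 CPM, Hmox1 by 1.99 (SE 0.05), and P2rx7, an ATP-gated channel, from 1.57 ± 0.199 to 182 ± 32.2 CPM.

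Of 130 developmental regulators 54 rose and 5 fell (56 and 6 adjusted over the list alone; median 0.73, or 0.70 at the bound; adjusted p = 1.2e-07, and 0.158 as the adjusted p with an estimated correlation). Neurog2, a proneural factor at 0 counts in both vehicle libraries, was at least 44.0-fold higher, and Ebf3 rose from 0.136 ± 0.0603 to 2.64 ± 0.0183 CPM. Ccdc81, also at 0 before, was at least 97.1-fold higher. Tfap2c, a factor of trophoblast and germ cells, rose by 1.43 (SE 0.07) and the collagen chaperone gene Serpinh1 by 1.19 (SE 0.04).

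Of 39 germline genes 14 rose and 3 fell (14 and 4 adjusted over the list alone; median 0.13, camera adjusted p = 0.013, and adjusted p = 0.317 with an estimated correlation). Tuba3b rose from 2.97 ± 0.156 CPM by 2.33 (SE 0.11) log2, Taf7l from 2.12 ± 0.169 to 8.18 ± 1.29 CPM, and Sycp3, which overlaps another gene, from 2.16 ± 0.0708 to 6.52 ± 0.466 CPM. Mael rose by 0.79 (SE 0.07) and Dazl by 0.74 (SE 0.08), from 9.27 ± 0.979 to 15.5 ± 0.17 CPM. Sycp1 stood at 5.15 ± 0.218 against 5.54 ± 0.0486 CPM (adjusted p = 0.518). Tex11 fell by 0.33 (SE 0.10), a call lost without wild-type inhibitor replicate 2 (-0.30, adjusted p = 0.0604), where adjusted p ranged from 0.00751 to 0.0604 over its alternatives. Meiosis genes rose in 13 of 40 and fell in 3 (adjusted p = 0.021, and 0.363 as the adjusted p with an estimated correlation).

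Of 40 pluripotency genes 19 fell and 7 rose (19 and 9 adjusted over the list alone; median -0.16, adjusted p = 0.0062, and 0.363 as the adjusted p with an estimated correlation). Sox2 fell from 440 ± 19.4 to 263 ± 0.875 CPM (-0.74, SE 0.04), Fgf4 fell by 0.66 (SE 0.04), the Nodal antagonist gene Lefty1 by 1.39 (SE 0.07) and Nanog by 0.20 (SE 0.04). Of 14 mitochondrial genes 11 fell and none rose (median -0.51, adjusted p = 0.00013, and 0.433 as the adjusted p with an estimated correlation). Among them mt-Nd1, which overlaps another gene, fell by 1.52 (SE 0.08) and mt-Co2 by 0.83 (SE 0.05). Small nucleolar RNA features, which poly(A) selection should not capture well, had a median of -1.64, with 57 of 82 falling and none rising. Rises also led in endoderm markers (11 of 27, 3 falling; adjusted p = 0.0038, and 0.158 as the adjusted p with an estimated correlation), the integrated stress response (19 of 40, 3 falling; 0.0044 and 0.26) and p53 targets (19 of 41, 4 falling; 0.0044 and 0.26).

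Of the targeted genes, Dnmt3a, which overlaps another gene, fell by 0.21 (SE 0.05), and Dnmt3b by 0.33 (SE 0.05). Dnmt1 fell by 0.17 (SE 0.05), a call lost without wild-type inhibitor replicate 2 (-0.12, adjusted p = 0.122, over a range from 0.00445 to 0.122). Tet1 fell by 0.17 (SE 0.06), a call lost without wild-type vehicle replicate 1 (-0.11, adjusted p = 0.209), without wild-type inhibitor replicate 2 (-0.10, adjusted p = 0.313) and in DESeq2, over a range from 0.00544 to 0.313. The edgeR test called 3171 genes up and 3120 down, of which 964 and 200 changed by more than 2-fold.

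The inhibitor was then compared with vehicle in TKO cells. Heat shock genes rose: 20 of 23 rose and none fell, the same adjusted over the list alone (median 0.42, adjusted p = 2.2e-10, and 0.181 as the adjusted p with an estimated correlation). Hspa1b rose from 14.6 ± 1.16 to 3100 ± 256 CPM and Hspa1a, with the limits on its reads named above, from 2.17 ± 0.0794 to 1208 ± 91.4 CPM. Hsph1 rose by 2.49 (SE 0.05), Dnajb1 by 2.19 (SE 0.06), Hmox1 by 1.05 (SE 0.04) and Atf3 by 1.03 (SE 0.11), and P2rx7 rose from 2.97 ± 0.557 to 191 ± 24 CPM.

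Of 39 germline genes 20 rose and 4 fell (21 and 4 adjusted over the list alone; median 0.27, camera adjusted p = 0.00017, and adjusted p = 0.212 with an estimated correlation). Tuba3b rose from 13.1 ± 0.192 to 45.7 ± 3.14 CPM (1.80, SE 0.08), Taf7l from 7.97 ± 0.339 to 18.1 ± 2.37 CPM (1.18, SE 0.11), Mael from 15.1 ± 1.01 to 31.6 ± 1.9 CPM (1.07, SE 0.08) and Sycp3, which overlaps another gene, by 1.88 (SE 0.16). Dazl rose by 0.42 (SE 0.05), from 87.3 ± 2.97 to 117 ± 2.96 CPM, and Sycp1 fell by 0.60 (SE 0.10). Stra8, which acts at meiotic entry, fell by 0.21 (SE 0.06), a call lost without TKO inhibitor replicate 2 (-0.11, adjusted p = 0.178, over a range from 0.000235 to 0.178). Nxf2, an X-linked gene of the testis, rose from 2.08 ± 0.229 to 31.1 ± 3.92 CPM, and Zscan4d fell by 0.90 (SE 0.13).

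Of 40 pluripotency genes 25 fell and 4 rose, the same adjusted over the list alone (median -0.24, adjusted p = 8.8e-06, and 0.263 as the adjusted p with an estimated correlation). Sox2 fell from 403 ± 2.63 to 180 ± 5.67 CPM (-1.16, SE 0.04), Tdgf1 fell by 1.02 (SE 0.05), Lefty1 by 1.58 (SE 0.07) and Nanog by 0.46 (SE 0.04). Of 28 trophoblast markers 19 rose and 2 fell (median 0.41, adjusted p = 0.00017, and 0.263 as the adjusted p with an estimated correlation), with Krt18 rising by 0.55 (SE 0.06) and Tfap2c by 0.48 (SE 0.05). Developmental regulators rose in 47 of 130 and fell in 13 (47 and 14 adjusted over the list alone; adjusted p = 0.017, and 0.352 as the adjusted p with an estimated correlation). Integrated stress response genes rose in 21 of 40 and fell in 1 (adjusted p = 0.00017, and 0.212 as the adjusted p with an estimated correlation). Of 14 mitochondrial genes 9 fell and none rose (adjusted p = 0.001, and 0.604 as the adjusted p with an estimated correlation), and mt-Nd1, which overlaps another gene, fell by 1.33 (SE 0.08). Small nucleolar RNA features had a median of -1.12.

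Dnmt1 rose by 0.23 (SE 0.05). Dnmt3b rose by 0.19 (SE 0.06), a call lost without TKO vehicle replicate 1 (0.12, adjusted p = 0.251) or TKO inhibitor replicate 1 (0.12, adjusted p = 0.245), over a range from 0.0167 to 0.251. The overlapping gene Dnmt3a had -0.09 (adjusted p = 0.175). Tet1 had -0.15 (adjusted p = 0.0524), and was called without TKO vehicle replicate 1 (-0.28, adjusted p = 0.00151) and with library size only, over a range from 0.00151 to 0.676. The edgeR test called 3324 genes up and 3272 down, 907 and 211 by more than 2-fold. Of these, 2038 also rose and 2080 also fell in wild-type cells, against 630.8 and 610.9 if the calls were independent, and Pearson's r across 16711 genes was 0.689, although genes are not independent replicates.

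Both perturbations together were compared with neither. Of 39 germline genes 33 rose and 3 fell, the same adjusted over the list alone (median 1.01, camera adjusted p = 3.4e-07, and adjusted p = 0.133 with an estimated correlation). Dazl rose from 9.27 ± 0.979 to 117 ± 2.96 CPM (3.66, SE 0.07), Fkbp6 from 1.41 ± 0.121 to 48.0 ± 0.222 CPM (5.08, SE 0.10), Tuba3b from 2.97 ± 0.156 to 45.7 ± 3.14 CPM (3.94, SE 0.10) and Taf7l from 2.12 ± 0.169 to 18.1 ± 2.37 CPM (3.08, SE 0.14). Mael, on chromosome 1, whose median was 0.51 below the other autosomes, rose by 0.56 (SE 0.07). Sycp3, which overlaps another gene, rose by 1.53 (SE 0.15). The falls included Brdt, by 2.95 (SE 0.18), and Tex11, by 0.88 (SE 0.10).

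X-linked germline genes rose in 35 of 37 and fell in 1 (adjusted p = 1.3e-11, and adjusted p = 0.0282 with an estimated correlation), and all 27 tested 2-cell-stage genes rose (3.5e-08 and 0.136). Developmental regulators rose in 94 of 130 and fell in 18 (median 2.63, 6.3e-07 and 0.136), with Hand1 up by 7.47 (SE 0.15), and Hox genes rose in 16 of 23 and fell in 4 (0.03 and 0.208), with Hoxd13 up by 3.44 (SE 0.17). Trophoblast markers rose in 25 of 28 and fell in 2 (3.5e-08 and 0.136), with Krt18 up by 4.56 (SE 0.07). H19, with its overlapping gene, rose by 11.69 (SE 0.09) and Hspa1a, likewise overlapping, by 10.17 (SE 0.14). Pluripotency genes fell in 25 of 40 and rose in 9 (median -0.57, 0.0048 and 0.237), with Sox2 down by 1.29 (SE 0.04), Nanog by 0.90 (SE 0.04) and Klf5 by 2.91 (SE 0.07). Each pair in parentheses gives the adjusted p of camera with the preset and then with an estimated correlation. Dnmt1 fell by 1.51 (SE 0.05), Dnmt3b by 1.96 (SE 0.06) and Dnmt3a, overlapping another gene, by 1.38 (SE 0.05). With edgeR 6612 genes were called up and 6125 down, 3847 and 1337 by more than 2-fold. Library size scaling alone shifted the median of all genes by 0.14 here and gave 61.5% of calls rising against 51.9%.

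**Figure D2:**
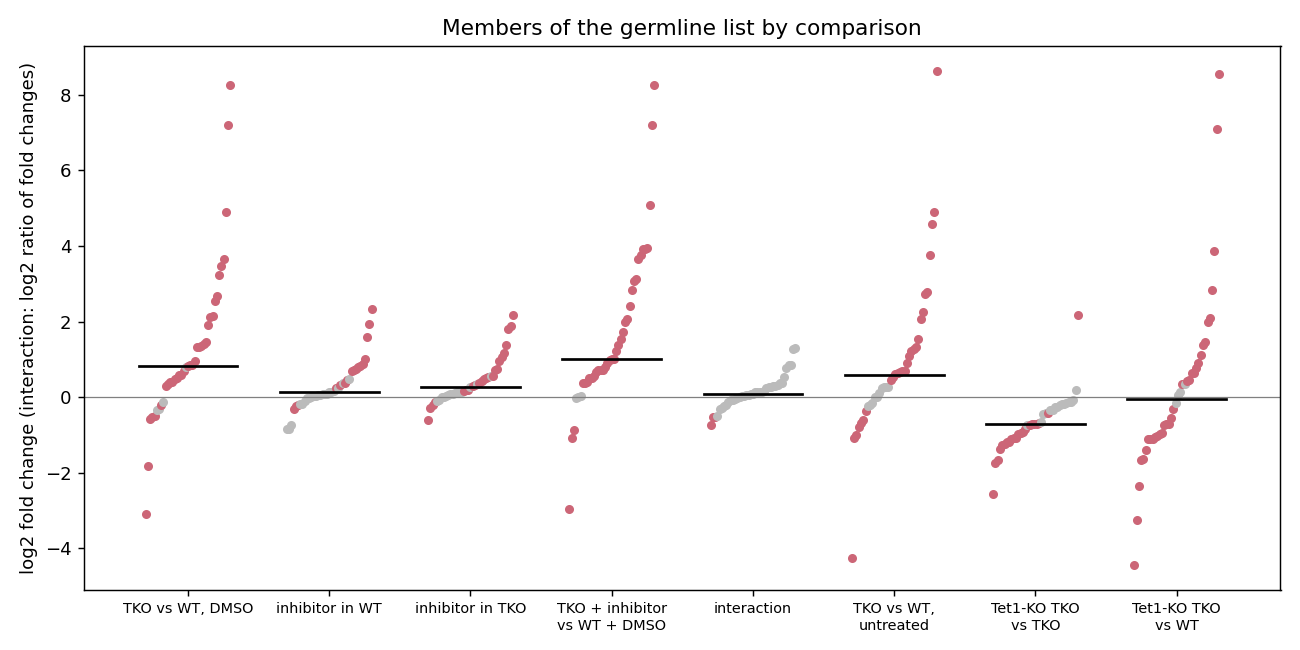
Log2 fold change of each tested member of the germline list, 39 genes in experiment 1 and 38 in experiment 2, in the 8 comparisons, coloured where called by edgeR, with a line at the median. The median was 0.81 for TKO against wild type under vehicle, 1.01 with the inhibitor added and -0.71 for Tet1-KO TKO against TKO.

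Whether the inhibitor's effect differed with genotype was tested by the interaction, the inhibitor's log2 change in TKO minus that in wild-type cells. A negative value means that the change in TKO cells was lower. For genes near 0 in wild-type and higher in TKO vehicle cells, it can in part reflect this starting level. The same added count gives a larger log2 change from a lower level. Of 27 endoderm markers 9 had lower and none higher changes (0 and 12 adjusted over the list alone, higher and lower; median -0.35, camera adjusted p = 9.4e-11, and adjusted p = 0.0378 with an estimated correlation). Serpinh1 (-0.76, SE 0.06), the laminin gene Lama1 (-0.56, SE 0.07) and the collagen gene Col4a1 (-0.55, SE 0.06), which overlaps another gene, were among the genes with lower changes. Of 130 developmental regulators 11 had lower and none higher changes (18 and 0 adjusted over the list alone; median -0.47, or -0.38 with the 8 members at 0 in a group placed at their floor, camera adjusted p = 2.5e-05, and adjusted p = 0.209 with an estimated correlation), among them Pax6 (-1.42, SE 0.27), Ebf3 (-2.79, SE 0.52) and Zic2 (-1.39, SE 0.14). Tfap2c (-0.95, SE 0.09), Mycn (-1.25, SE 0.09) and Sox2 (-0.42, SE 0.06) also had lower changes.

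Members of the integrated stress response list went both ways, with Atf3 lower (-2.55, SE 0.18, adjusted p = 1.3e-09) and Atf4 higher (0.62, SE 0.06). Of its 40 genes 2 had higher and 3 lower changes (4 and 5 adjusted over the list alone; median 0.04, mean -0.06, camera adjusted p = 0.848 in the upward direction). Of 23 heat shock genes none had a higher and 4 a lower change (0 and 6 adjusted over the list alone; median -0.05, adjusted p = 0.0394, and 0.328 as the adjusted p with an estimated correlation), among them the co-chaperone gene Bag3 (-1.32, SE 0.10). Of 35 NRF2 targets none had a higher and 3 a lower change (0 and 4 adjusted over the list alone; median -0.11, adjusted p = 0.0036, and 0.32 as the adjusted p with an estimated correlation), among them Hmox1 (-0.94, SE 0.07).

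Of 39 germline genes none had a higher and 3 a lower change in TKO cells (2 and 6 adjusted over the list alone; median 0.09, camera adjusted p = 0.197). The 3 were Taf7l (-0.75, SE 0.20, adjusted p = 0.0367), Tuba3b (-0.52, SE 0.14, adjusted p = 0.0372) and Smc1b (-0.53, SE 0.14, adjusted p = 0.0356). Each of these calls was lost in DESeq2 and in 5 or more of 8 leave-one-out fits. Taf7l had -0.68 without wild-type vehicle replicate 1, -0.72 and -0.80 without TKO vehicle replicates 1 and 2, -0.60 without wild-type inhibitor replicate 2 and -0.63 without TKO inhibitor replicate 1, with adjusted p from 0.0206 to 0.149 over its alternatives. Tuba3b had -0.48 and -0.58 without wild-type vehicle replicates 1 and 2, -0.52 and -0.55 without TKO vehicle replicates 1 and 2, -0.56 and -0.49 without wild-type inhibitor replicates 1 and 2, and -0.47 without TKO inhibitor replicate 1, with adjusted p from 0.0334 to 0.106. Smc1b had -0.37 without wild-type vehicle replicate 2, -0.53 and -0.55 without TKO vehicle replicates 1 and 2, -0.40 without wild-type inhibitor replicate 1 and -0.48 without TKO inhibitor replicate 1, with adjusted p from 0.00808 to 0.257. Not called were Sycp3 (0.30, adjusted p = 0.551), which overlaps another gene, Mael (0.28, adjusted p = 0.16) and Sycp1 (-0.49, adjusted p = 0.0811). Dazl had -0.32 (adjusted p = 0.0652) and was called without wild-type vehicle replicate 1 (-0.43, adjusted p = 0.0156), over a range from 0.0156 to 0.305.

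Higher changes in TKO cells were called for the myosin gene Myh14 (2.17, SE 0.12), which overlaps another gene, the sodium channel gene Scn8a (2.05, SE 0.23), Peg10 (0.67, SE 0.07), Peg3 (0.55, SE 0.09), Dnmt1 (0.40, SE 0.07), Dnmt3b (0.51, SE 0.08) and mt-Co2 (0.41, SE 0.07). Hsph1 had a lower change (-0.35, SE 0.07), a call lost without TKO vehicle replicate 2 (-0.31, adjusted p = 0.0632, over a range from 0.00081 to 0.0632). Nanog had a lower change (-0.27, SE 0.06), a call lost without TKO vehicle replicate 1 (-0.26, adjusted p = 0.0862) or wild-type inhibitor replicate 1 (-0.25, adjusted p = 0.0516), over a range from 0.00145 to 0.0862. The edgeR test called 295 genes higher and 355 lower, 650 in all, 32 and 116 of them by more than 2-fold, with 2974 genes at an unadjusted p under 0.05. The 650 became 304 without TKO vehicle replicate 2, 343 without its replicate 1, 377 and 386 without TKO inhibitor replicates 2 and 1, 382 without wild-type inhibitor replicate 2, and 913 without wild-type vehicle replicate 1, while DESeq2 gave 417.

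**Figure D3:**
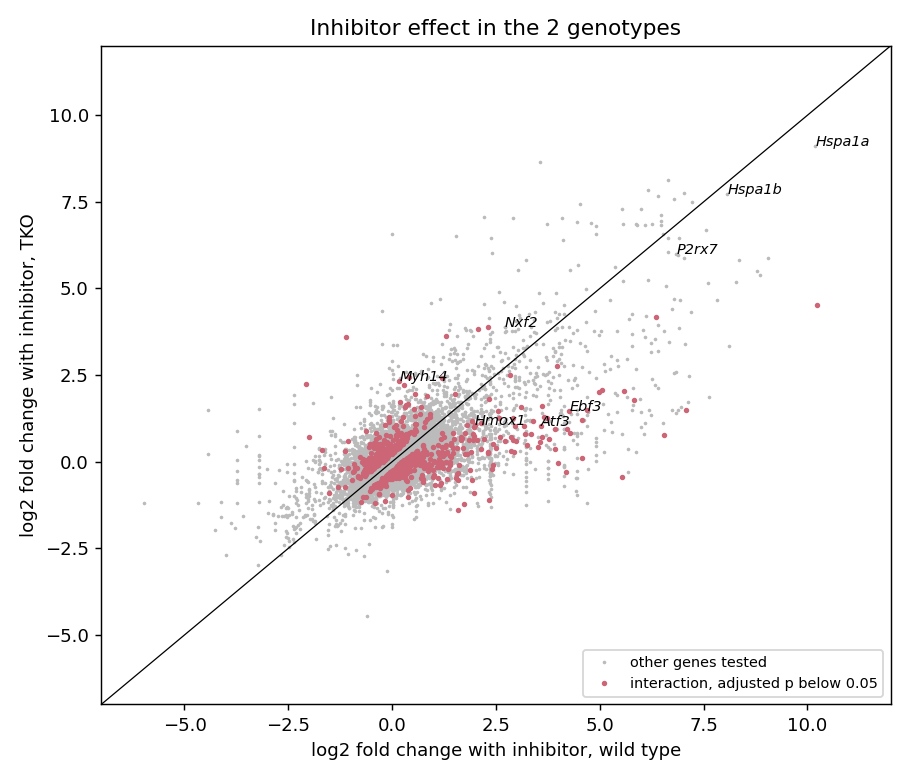
Log2 fold change with the inhibitor in wild-type cells (x axis) and in TKO cells (y axis) for the 16711 genes tested, with the 650 genes called for the interaction in colour and the line of equal change. Hspa1a and Hspa1b lie at the top right and Atf3 lies below the line, at 3.58 in wild-type and 1.03 in TKO cells.

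The comparison of untreated TKO with untreated wild-type cells asked the first question again in other libraries. Genotype and line are confounded here as well. Agreement between the experiments therefore cannot separate methyltransferase loss from other differences between the lines. Of 38 germline genes 21 rose and 7 fell, the same adjusted over the list alone (median 0.58, camera adjusted p = 0.0078, and adjusted p = 0.386 with an estimated correlation). Dazl rose from 11.3 ± 0.419 to 53.5 ± 3.49 CPM (2.24, SE 0.11), Fkbp6 from 1.26 ± 0.281 to 29.6 ± 0.892 CPM (4.57, SE 0.18) and Smc1b from 6.83 ± 0.0182 to 46.6 ± 7.19 CPM (2.77, SE 0.16). Hormad1 rose by 2.06 (SE 0.21), Tdrd12 by 3.55 (SE 0.11), Rpl10l by 1.53 (SE 0.12) and Taf7l by 1.23 (SE 0.23). Brdt fell by 4.25 (SE 0.27) and Mael by 0.60 (SE 0.14), with chromosome 1, which holds Mael, at a median 0.52 below the other autosomes. Sycp3, which overlaps another gene, fell by 0.99 (SE 0.26), a call lost without wild-type replicate 2 (-0.66, adjusted p = 0.0777, over a range from 0.00201 to 0.0777). Ddx4 had -0.23 (adjusted p = 0.145) and was called without wild-type replicate 1 (-0.37, adjusted p = 0.0366, over a range from 0.0366 to 0.61).

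X-linked germline genes rose in 37 of 38 and none fell (median 5.80, or 4.73 at the bound; adjusted p = 8.7e-18, and 0.386 as the adjusted p with an estimated correlation). Xlr3c rose from 0.459 ± 0.349 to 34.7 ± 2.03 CPM and Rhox9 from 0.238 ± 0.0374 to 13.5 ± 2.27 CPM. Of 27 genes of the 2-cell stage 25 rose and none fell (median 3.40, or 3.32 at the bound; adjusted p = 4.7e-10, and 0.386 as the adjusted p with an estimated correlation), with Tmem92 up by 5.90 (SE 0.29) and Zscan4c by 3.69 (SE 0.27). Imprinted genes rose in 27 of 52 and fell in 13 (adjusted p = 0.028, and 0.537 as the adjusted p with an estimated correlation). Among them H19, overlapping another gene, rose from 1.15 ± 0.125 to 570.4 ± 28.8 CPM, Plagl1 rose by 6.79 (SE 0.36) and Peg3 by 3.01 (SE 0.12). Developmental regulators rose in 57 of 98 and fell in 17 (adjusted p = 3.6e-05, and 0.386 as the adjusted p with an estimated correlation), with Pax6 up by 6.51 (SE 0.29) and Prrx2 down by 4.15 (SE 0.21). Trophoblast markers rose in 20 of 27 and fell in 3 (adjusted p = 4.5e-05, and 0.39 as the adjusted p with an estimated correlation), with Krt18 up by 2.20 (SE 0.14) and Tead4 down by 2.37 (SE 0.17). Endoderm markers fell in 10 of 26 and rose in 3, the same adjusted over the list alone (median -0.75, camera adjusted p = 0.198, or adjusted p = 0.0072 with the replicate block, and adjusted p = 0.592 with the block and an estimated correlation).

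Klf5 fell by 2.89 (SE 0.15), Tbx3, which overlaps another gene, by 2.57 (SE 0.12), Atf4 by 1.97 (SE 0.13) and Nkx6-3, on chromosome 8, from 17.6 ± 2.4 to 0.239 ± 0.064 CPM, while Dppa3 rose by 5.85 (SE 0.24). Nanog fell by 0.45 (SE 0.12), a call lost without TKO replicate 2 (-0.34, adjusted p = 0.126, over a range from 0.00118 to 0.126). Sox2 fell by 0.38 (SE 0.10), a call lost without TKO replicate 1 (-0.40, adjusted p = 0.0623) or 2 (-0.36, adjusted p = 0.0892), over a range from 0.00115 to 0.0892. Pou5f1, overlapping another gene, fell by 0.42 (SE 0.10), a call lost without TKO replicate 1 (-0.40, adjusted p = 0.0577, over a range from 8.3e-05 to 0.0577). Dnmt1 fell from 346 ± 58.2 to 122 ± 7.98 CPM (-1.50, SE 0.12), Dnmt3b by 1.55 (SE 0.11), Dnmt3a, overlapping another gene, by 0.97 (SE 0.14) and Tet2 by 0.74 (SE 0.11). Dnmt3l, likewise overlapping, rose by 2.93 (SE 0.13). Tet1 rose by 0.45 (SE 0.16), a call lost without wild-type replicate 2 (0.37, adjusted p = 0.118), TKO replicate 1 (0.41, adjusted p = 0.122) or TKO replicate 2 (0.50, adjusted p = 0.052), over a range from 0.00757 to 0.122.

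The edgeR test called 4228 genes up and 3959 down, 2362 and 1379 by more than 2-fold. With the replicate block it called 4501 up and 4289 down. Of the genes that rose under vehicle in experiment 1, 5520 were measured here and 65.7% of them rose, against 5.60% of the other genes, with a median of 0.76 (camera p = 8.6e-86, and p = 0.00045 with an estimated correlation). Calls were shared for 3624 rising genes, against 1441.7 for independent calls, and 3301 falling genes, against 1401.2. Across 15878 genes Pearson's r was 0.884 and Spearman's rho 0.823, although genes are not independent replicates. Genes that rose in untreated TKO cells had a median of 0.06 with the inhibitor in wild-type cells (camera p = 0.0765, and p = 0.0439 with an estimated correlation), -0.02 in TKO cells (p = 0.4) and -0.09 in the interaction (p = 0.00012, and p = 0.0032 with an estimated correlation). Those that rose more than 2-fold had a median of 0.26 in wild-type cells (p = 4.5e-05, and p = 0.0013 with an estimated correlation), 0.00 in TKO cells (p = 0.886) and -0.27 in the interaction (p = 2.1e-08, and p = 0.00037 with an estimated correlation). Both sets were chosen as higher in TKO cells, so a lower log2 change there can in part come from that starting level.

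The comparison of Tet1-KO TKO with TKO cells asked what loss of Tet1 did without DNA methyltransferases. Genotype and line are confounded in it, so a change cannot be assigned to Tet1 loss alone. Tet1 fell from 766 ± 34.9 to 168 ± 47 CPM (-2.19, SE 0.16, adjusted p = 7.8e-06), with 134 and 201 CPM in the 2 libraries. Of 38 germline genes 21 fell and 1 rose (24 and 1 adjusted over the list alone; median -0.71, camera adjusted p = 4.1e-10, and adjusted p = 0.194 with an estimated correlation). Stra8 fell from 37.9 ± 9.31 to 6.41 ± 1.6 CPM (-2.57, SE 0.20), Smc1b from 46.6 ± 7.19 to 14.8 ± 2.51 CPM (-1.65, SE 0.15), Rpl10l by 1.07 (SE 0.11), Piwil2, a piRNA-binding protein, by 0.94 (SE 0.11) and Ddx4, a germ cell helicase, by 0.71 (SE 0.12). The ferritin-like gene Fthl17a rose from 1.29 ± 0.137 to 5.85 ± 1.24 CPM. Dazl stood at 48.2 ± 0.369 against 53.5 ± 3.49 CPM (-0.15, adjusted p = 0.321) and was not called, nor were Sycp1 (-0.33, adjusted p = 0.144), Taf7l (-0.46, adjusted p = 0.152) and Sycp3 (-0.66, adjusted p = 0.103), which overlaps another gene and was called with the replicate block (-0.68, adjusted p = 0.0449). Mael had -0.42 (adjusted p = 0.0502), and was called with the replicate block (adjusted p = 0.0222), with DESeq2 size factors (adjusted p = 0.0494) and library size only (adjusted p = 0.0242), over a range from 0.0222 to 0.245. Hormad1 fell by 0.69 (SE 0.20), a call lost in DESeq2 (adjusted p = 0.162) and without Tet1-KO TKO replicate 1 (-0.59) or 2 (-0.79) or TKO replicate 2 (-0.57), over a range from 0.00131 to 0.162.

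Meiosis genes fell in 12 of 38 and rose in 1 (15 and 1 adjusted over the list alone; adjusted p = 7.7e-06, and 0.48 as the adjusted p with an estimated correlation), with Meioc, which sustains meiotic prophase, down by 2.18 (SE 0.18). piRNA genes fell in 14 of 29 and rose in 2 (7.7e-06 and 0.194), with Tdrd12 down by 0.65 (SE 0.10). X-linked germline genes fell in 22 of 38 and rose in 3 (6.4e-06 and 0.48). Xlr3c fell by 2.15 (SE 0.20), whereas Rhox6 rose from 22.4 ± 1.73 to 78.1 ± 0.72 CPM and Rhox9 from 13.5 ± 2.27 to 45.9 ± 3.88 CPM. Of 27 genes of the 2-cell stage 19 fell and 1 rose (median -1.42, 9e-08 and 0.48), with Tmem92 down by 2.22 (SE 0.20) and Zscan4f by 2.07 (SE 0.31). The pairs in parentheses are the adjusted p of camera with the preset and then with an estimated correlation.

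Trophoblast markers rose in 23 of 27 and none fell (24 and 1 adjusted over the list alone; median 1.26, adjusted p = 3.9e-10, and 0.303 as the adjusted p with an estimated correlation). Krt18 rose from 43.4 ± 2.9 to 182 ± 30.8 CPM, Krt8 from 82.1 ± 6.28 to 335 ± 80.4 CPM, Hand1 by 1.52 (SE 0.20) and Eomes, a factor of trophoblast stem cells, by 1.76 (SE 0.19). H19, overlapping another gene, rose by 1.66 (SE 0.10) and Sfmbt2 by 1.35 (SE 0.13). Endoderm markers rose in 12 of 26 and none fell (20 and 1 adjusted over the list alone; adjusted p = 0.0009, and 0.687 as the adjusted p with an estimated correlation), with Sparc, a matrix protein of parietal endoderm, up by 0.91 (SE 0.17). Sox17 rose by 1.36 (SE 0.32), a call lost in DESeq2 (adjusted p = 0.0641) and without Tet1-KO TKO replicate 2 (0.90, adjusted p = 0.0929) or TKO replicate 1 (1.00, adjusted p = 0.069), over a range from 9.05e-06 to 0.0929. Cholesterol synthesis genes rose in 10 of 24 and none fell (adjusted p = 0.00011, and 0.616 as the adjusted p with an estimated correlation), with Sqle up by 0.65 (SE 0.12) and Cyp51, overlapping another gene, by 0.62 (SE 0.09). Glycolysis genes rose in 10 of 33 and fell in 2 (0.0016 and 0.616), and p53 targets rose in 13 of 41 and fell in 1 (0.0016 and 0.234). Rnf128, a ubiquitin ligase gene, rose by 3.01 (SE 0.15), while Pax6 fell by 1.92 (SE 0.19).

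Dnmt3a, overlapping another gene, fell by 1.04 (SE 0.15), and Dnmt3b had 0.30 (adjusted p = 0.0729, and adjusted p = 0.0301 with the replicate block, where it was called). Tet2 fell by 0.36 (SE 0.11), a call lost without Tet1-KO TKO replicate 1 (-0.25, adjusted p = 0.261) or TKO replicate 1 (-0.28, adjusted p = 0.291) or 2 (-0.44, adjusted p = 0.0917), over a range from 0.0177 to 0.291. Nanog had 0.12 (adjusted p = 0.536) and Dnmt1 -0.06 (adjusted p = 0.77), and neither was called. Without Tet1-KO TKO replicate 1 the value for Nanog was -0.03 (adjusted p = 0.921, over a range from 0.249 to 0.984), and without TKO replicate 2 that for Dnmt1 was 0.01 (adjusted p = 0.98, over a range from 0.521 to 0.98). The edgeR test called 1895 genes up and 1689 down, 536 and 765 by more than 2-fold, and library size scaling alone gave 40.6% of calls rising against 52.9%. With the replicate block 2366 were called up and 2132 down. The 3584 calls became 1633 without TKO replicate 1, 1721 without TKO replicate 2 and 2214 without Tet1-KO TKO replicate 2. Genes that rose in TKO cells under vehicle in experiment 1 had a median of -0.05 here (camera p = 0.21, and p = 0.36 with an estimated correlation).

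Against untreated wild-type cells, Tet1-KO TKO cells had 16 germline genes higher and 18 lower of 38 (17 and 18 adjusted over the list alone; median -0.05, mean 0.26, camera adjusted p = 0.593 in the downward direction). Dazl rose from 11.3 ± 0.419 to 48.2 ± 0.369 CPM (2.09, SE 0.11), Fkbp6 by 3.86 (SE 0.18) and Smc1b by 1.12 (SE 0.16). Stra8 fell from 61.1 ± 9.51 to 6.41 ± 1.6 CPM (-3.25, SE 0.20), Mael, on chromosome 1, by 1.02 (SE 0.14), Ddx4 by 0.94 (SE 0.12) and Brdt by 4.45 (SE 0.27). Genes of chromosome 1 had a median 0.46 below the other autosomes here.

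X-linked germline genes rose in 36 of 38 and fell in 1 (adjusted p = 1.4e-14, and 0.297 as the adjusted p with an estimated correlation), with Rhox6 up by 5.67 (SE 0.16). Genes of the 2-cell stage rose in 20 of 27 and none fell (9.1e-06 and 0.535), with Tmem92 up by 3.69 (SE 0.32), and trophoblast markers rose in 24 of 27 and fell in 2 (6.8e-09 and 0.297), with Krt18 up by 4.27 (SE 0.15). H19, overlapping another gene, rose by 10.60 (SE 0.16) and Dppa3 by 6.95 (SE 0.23), while Klf5 fell by 2.52 (SE 0.15), Prrx2 by 4.83 (SE 0.22) and Igsf21 by 6.35 (SE 0.18). Tet1 fell by 1.74 (SE 0.16), Dnmt1 by 1.56 (SE 0.12), Dnmt3b by 1.24 (SE 0.11) and Dnmt3a, overlapping another gene, by 2.01 (SE 0.15). With edgeR 4289 genes were called up and 3981 down, 2335 and 1594 by more than 2-fold, and with the replicate block 4540 up and 4286 down.

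**Figure D4:**
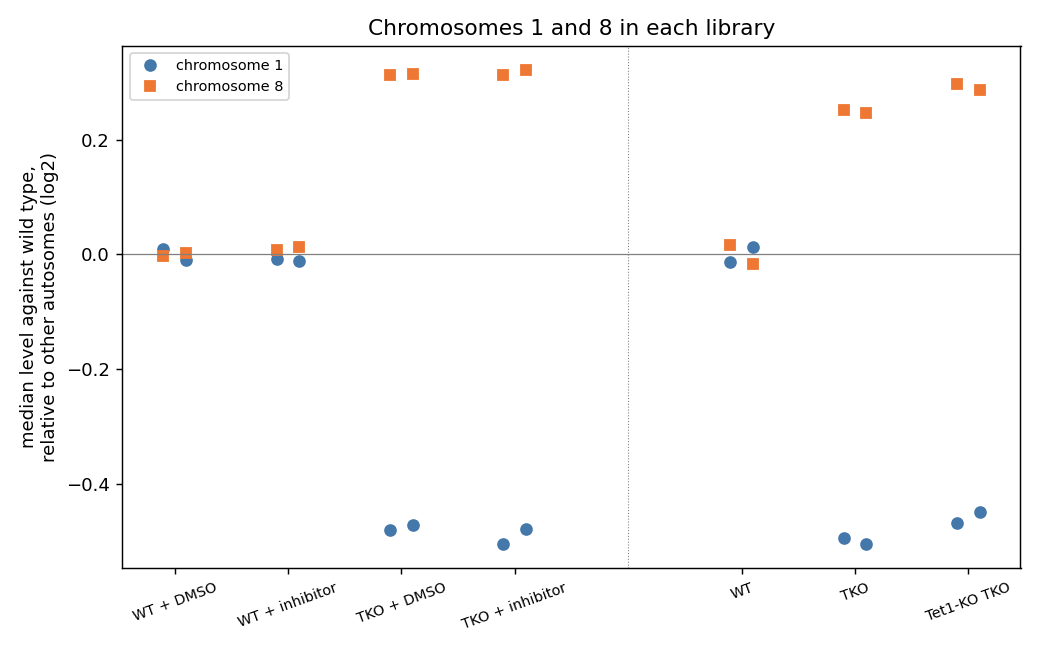
Median log2 level of the genes of chromosome 1 and of chromosome 8 against wild type, relative to the other autosomes, with 1 point per library and chromosome and the groups along the x axis. Chromosome 1 lay between -0.45 and -0.51 in the libraries of TKO and Tet1-KO TKO cells and within 0.013 of 0 in those of wild-type cells.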

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

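The interaction test and its gene lists were planned, while the tests of the rise of near-silent genes were chosen after that rise was seen, and their final form after earlier ones. The inhibitor's log2 change differed between TKO and wild-type cells for 650 genes, by the edgeR interaction test.

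Among gene lists, the change in TKO cells was lower for X-linked germline genes (median -0.36), 2-cell-stage genes (-1.05), developmental regulators (-0.47), pluripotency (-0.13), endoderm markers (-0.35) and neural ectoderm markers (-0.24). It was also lower for p53 targets (-0.17), NRF2 targets (-0.11), heat shock genes (-0.046), AhR targets (-0.86) and glycolysis (-0.13), and higher for mitochondrial genes (0.18). With members at 0 in a group placed at their floor the medians were -0.28 for X-linked germline genes, -0.38 for developmental regulators and -0.20 for neural ectoderm markers, while the other 9 did not move. Only 8 AhR targets were tested. Under vehicle, TKO cells already had higher medians than wild type, 4.70 for X-linked germline, 4.61 for 2-cell-stage and 1.80 for developmental genes at the bound. The same held for AhR targets (2.57), neural ectoderm markers (0.918) and p53 targets (0.425) at the bound. Medians of pluripotency, endoderm, NRF2, heat shock and glycolysis genes were below 0 there. For the lists that started higher, negative differences can in part come from this starting level, and how far was not tested. With an estimated correlation only the endoderm call held (adjusted p = 0.0378).

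Among named genes the difference was negative for Atf3 (-2.55), Hmox1 (-0.94), Bag3 (-1.32), Hsph1 (-0.35), Tfap2c (-0.95), Serpinh1 (-0.76), Lama1 (-0.56), Col4a1 (-0.55), Sox2 (-0.42), Nanog (-0.27) and Mycn (-1.25). It was also negative for Pax6 (-1.42), Ebf3 (-2.79), Zic2 (-1.39), Taf7l (-0.75), Tuba3b (-0.52) and Smc1b (-0.53). It was positive for Myh14 (2.17), Scn8a (2.05), Peg10 (0.67), Peg3 (0.55), Atf4 (0.62), Dnmt1 (0.40), Dnmt3b (0.51) and mt-Co2 (0.41).

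Many genes below 0.5 CPM in wild-type vehicle cells rose more than 2-fold with the inhibitor, among them 526 of 3832 protein-coding and lincRNA genes with a count there in a fit without filter, and 2 explanations were tested. Developmental regulators, a class of polycomb targets, rose in 34 of 75 against 492 of 3757 others, 3.46 times as often (Fisher's exact p = 1.9e-11). Over every near-silent gene of the table they rose 5.79 times as often. Camera had called the same list as rising in this comparison, so a higher share was likely in advance and is no independent support. Fisher's test also takes genes as independent. Release from PRC1 stays a hypothesis. Transcription running on from an upstream neighbour cannot be told apart from this: the excess of risen genes with an expressed neighbour was 5.13 percentage points larger upstream than downstream, or 8.24 points over every gene, between the bounds of 5 points against it and 10 for it. Earlier forms used genes kept by a filter that the rise itself could pass (2.27 times and 8.28 points) or all annotated neighbours (8.61 to 10.9 points), where 2 of 3 values passed the bound for it but at most 70.6% of the risen genes had both neighbours in the table, under the 80% needed. Stress from the compound itself was not tested.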

How the results depend on the processing

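All alternatives fixed beforehand were run, though not on every kind of result, and removal of genes of chromosomes 1, 8 and Y was added after the results were seen. Named genes were run with DESeq2 size factors, library size only, the replicate block, DESeq2 Wald tests and each library left out. The other alternatives were not applied to them. Of 245 results for named genes, 28 changed their side of the threshold or direction in any of these settings, and all are given with the genes. Of 119 counts under an alternative 100 were within 1.5 times the original. With a log2 fold change over 1 the counts were 4270 (TKO against wild type, vehicle), 1164 (inhibitor, wild type), 1118 (inhibitor, TKO), 5184 (both against neither), 148 (interaction), 3741 (TKO against wild type, untreated), 1301 (Tet1-KO TKO against TKO) and 3929 (Tet1-KO TKO against wild type), fewer by construction, as were 245 for the interaction and 1719 for Tet1-KO TKO against TKO at an adjusted p under 0.01. DESeq2 gave 417 for the interaction, and the cause was not tested. Leave-one-out counts ran from 304 to 913 for the interaction and from 1633 to 2468 for Tet1-KO TKO against TKO. A lone library was then assumed to vary like the other groups, and fewer samples left fewer residual degrees of freedom.

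With an estimated correlation camera no longer called the germline list: 0.81 (adjusted p = 0.113) under vehicle, 0.13 (0.317) and 0.27 (0.212) for the inhibitor in wild-type and TKO cells, 0.58 (0.386) in untreated TKO and -0.71 (0.194) for Tet1-KO TKO against TKO. Values that changed sign were 0.024 for Sox2 in TKO against wild type with library size only and, in Tet1-KO TKO against TKO, leave-one-out values of -0.029 to 0.254 for Nanog and -0.119 to 0.012 for Dnmt1, and the cause was not tested. Genes that rose in untreated TKO cells had 0.061 (p = 0.0439) with the inhibitor in wild-type cells with an estimated correlation, and those over 2-fold had 0.26 (p = 4.5e-05) there, 0 (p = 0.886) in TKO cells and -0.27 (p = 2.1e-08) in the interaction. With a replicate block the counts in experiment 1 ran from 632 for the interaction to 12673 for both against neither, and no call of a named gene or of the germline list changed. In experiment 2 they were 8790, 4498 against 3584 without it for Tet1-KO TKO against TKO, and 8826 for Tet1-KO TKO against wild type, and besides the calls of Mael, Sycp3, Dnmt3b and the endoderm list given with these, it changed no call of a named gene or a list. Without chromosomes 1, 8 and Y the germline list had 0.81 (adjusted p = 0.0002) under vehicle and 0.50 (adjusted p = 0.018) in untreated cells. Depth limits calls near the filter, and in experiment 2 a 1.5-fold change was recovered for 34.3% of simulated genes.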

Other observations

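The tests of chromosome dosage and of a single aberrant library were applied to chromosome 1 after its low median was seen. Those of the trophoblast genes were chosen after their rise was seen.

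The Y-linked genes were low in wild-type and higher in TKO libraries of both experiments. Summed over Y-linked genes, levels were 6.11 and 6.84 CPM in the wild-type and 233 and 234 CPM in the TKO vehicle libraries. Genotype and line are confounded here, so the difference cannot be assigned to loss of the methyltransferases. Uty stood at 0.561 ± 0.0861 CPM in wild-type and 29.6 ± 0.0776 CPM in TKO vehicle cells, and Eif2s3y at 3.8 ± 0.427 and 78.8 ± 3.29 CPM. In untreated cells Ddx3y stood at 1.76 ± 0.443 CPM in wild type, 114 ± 14.4 CPM in TKO and 125 ± 8.05 CPM in Tet1-KO TKO. Kdm5d had 0 counts in wild-type vehicle cells and 157 counts in TKO vehicle cells.

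Genes of chromosome 1 were lower in TKO than in wild-type libraries, by a median of 0.49 log2 under vehicle and 0.52 untreated. A single aberrant library is argued against by the gap of 0.436 between the wild-type library and the TKO or Tet1-KO TKO library that lay closest in an experiment. In both experiments each of 4 equal parts of the chromosome by gene order lay below the other autosomes, but not uniformly. In that order the differences were -0.585, -0.567, -0.489 and -0.238 under vehicle and -0.611, -0.544, -0.55 and -0.261 in untreated cells. The chromosome was picked for its low median, so low parts were likely in advance and are no independent support. A difference in chromosome 1 dosage between the lines stays a hypothesis. Which line would carry the altered dosage cannot be told from comparing them. An effect of genotype on these genes stays open, since genotype and line are confounded.

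Placental and trophoblast genes were higher in Tet1-KO TKO than in TKO cells, with 26 of 30 members that were at least 4-fold higher in TKO than wild type rising, by a median of 2.09. Reads shared between near-identical copies are argued against, since 13 members outside multi-copy families rose more than 2-fold. A larger share of trophoblast-type cells predicts 1 common factor and stays open: the 30 members deviated from their weighted mean by 2.04 of their own standard errors (root mean square), between the bounds of 2 for it and 3 against it, while an earlier form with the median standard error gave 1.69, against 3.46 for 1305 other genes with a 4-fold rise. In a split made afterwards the value was 3.03 for the 10 members outside multi-copy families, where Tfap2a (0.06, SE 0.28) and Gcm1 (-0.29, SE 0.49), singled out after their values were seen, lay lowest, and 1.18 for the 20 others, whose copies would rise alike if they share reads. More such cells therefore cannot be told apart from a direct effect of Tet1 loss, which was not tested. Nor can other differences between the 2 lines, since genotype and line are confounded here too.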
